A study of Mus musculus with 4 samples.

How the data were processed

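Total RNA from 4 cultures of mouse liver tumour-initiating stem-like cells was depleted of ribosomal RNA before library preparation, per the labels' protocols. The growth medium held serum, EGF and dexamethasone, per the labels' protocols. The vehicle culture's time in treatment is not given in the sources used here. Reads were trimmed with Trimmomatic 0.32 and expression was computed with Cuffdiff against the mouse build mm10, per the submitters' processing notes. The aligner, the Cuffdiff version, the gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments, with 1 column per library, per the file headers. No read counts were used here.

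The table held 23359 rows, 1 per gene symbol. In 27 rows the symbol had been turned into a date, and each was resolved from its description. Column totals were 266680 FPKM for vehicle, 304329 for ATRA, 258214 for SAHA and 309001 for the combination. The 10 highest rows held 46.9%, 47.2%, 59.5% and 46.4% of these totals, and small RNAs held 27.3%, 29.0%, 26.2% and 34.0%. These are shares of FPKM, which is divided by transcript length, so they overstate the share of reads for short transcripts. Depth was estimated from the smallest repeated step of FPKM times transcript length over about 880 low genes with transcripts of 1000 to 4000 bases (880, 832, 887 and 883 genes per library), taking 1 step as 1 fragment. The second step lay at 1.89, 2.10, 1.93 and 2.02 times the first. The FPKM values give no counting interval of their own, and none is printed. An exact 0 in such a table can be a failed estimate, so such genes are described as listed at 0 and no fold is given against them.

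Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were counted, 8616 in all, of which 148 were small RNAs by name or RefSeq type. With 1 library per group no test was run: a gene was called higher or lower at a log2 difference of 1 or more. The design written beforehand also foresaw a filter on a status column and a setting based on deposited intervals. The table used here holds neither, so both were left out. The 5 comparisons were each compound and the combination against vehicle, and the combination against each compound. The departure from additivity is the combination's log2 ratio minus the sum of the ratios of ATRA and SAHA. Genes expected in both of 2 independent lists were computed from the sizes of the lists and the number of counted genes.

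Before the data were examined, 55 gene lists with 1538 entries were fixed from general knowledge, and 1349 of their 1376 symbols were in the table. The median log2 ratio of each list with at least 5 counted members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. These percentiles describe these libraries and are not tests, and some genes stand in more than 1 list. Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest genes of each comparison with vehicle, and the 6 highest and 6 lowest of the others, with at least 5 FPKM in the higher library, leaving out predicted genes, joined symbols, pseudogenes and small RNAs by name prefix. Some small RNAs with other prefixes passed that rule and are named as such. The rule also names up to 4 leading members of each list described and a fixed set of retinoid, HDAC, stem cell and liver genes that are given whatever their values. Coordinates are from GENCODE release M21, on the mm10 assembly, and 99.5% of the 17808 loci compared overlapped those in the table. In the table, 1622 counted genes share a locus with another row, and reads from overlapping genes were not separated here. The sequence match to mitochondrial ribosomal RNA used BLAST+ 2.17.0 on GENCODE transcripts.

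The rule of size and the list percentiles were tested on simulated data. For a treated against vehicle comparison of 8468 genes, with noise of 0.155 on the log2 scale taken from the ATRA against vehicle differences, 49 of 50 genes raised by 1.5 and 49 of 50 lowered by 1.5 passed the 2-fold mark. Of genes raised or lowered by 3, 50 of 50 passed in each direction, and 0 of 8268 unchanged genes did. Of 3000 unchanged random lists in the same simulation, 170 (5.67%) lay outside the middle 95%. Among the first 200 of these lists, 17 (8.50%) did, and the number was then raised to 3000 to measure the rate better. The noise in the simulation comes from 2 libraries, was set alike for genes of all levels and does not replace replicates. With noise this small, almost no unchanged gene could pass the 2-fold mark, so that count gives no false call rate for these data. Alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, centring each library on its median log2 ratio to vehicle and, for lists, the mean in place of the median. Leaving out small RNAs was added after the data were seen. Calculations used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.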

Results

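RNA was sequenced from tumour-initiating stem-like cells, a cultured cell population taken from liver tumours of C57BL/6 mice. One culture received vehicle, one received all-trans retinoic acid (ATRA, the vitamin A metabolite that activates the retinoic acid receptors) at 5 µg/ml, one received suberoylanilide hydroxamic acid (SAHA, also called vorinostat, an inhibitor of histone deacetylases) at 0.5 µg/ml, and one received both compounds at these doses. Treatment lasted 16 hours. Each of the 4 groups had 1 library, so no difference given here has a replicate check, and no p-value or error is given. Differences are described by size: a gene was counted as higher or lower when its log2(FPKM + 1) differed by 1 or more, that is 2-fold on that scale. This scale understates the difference for low genes. Folds given in words are ratios of the FPKM values themselves. By an estimate from the lowest steps in the values, 1 FPKM over 1 kilobase stood for about 98.2, 102, 98.6 and 103 fragments in the vehicle, ATRA, SAHA and combination libraries. In the same order, 8542, 8388, 7781 and 8002 genes were at 1 FPKM or more.

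The 4 libraries showed what kind of cell was sampled. Vim, the intermediate filament of mesenchymal cells, was at 562 FPKM in the vehicle library, a gene chosen for mention after its value was seen. Krt18, an epithelial keratin, was at 95.3 FPKM and Cd44, a surface marker of many tumour stem cells, at 61.8 FPKM. Krt18 had the highest mean of the epithelial list, of which 7 of 36 genes reached a mean of 1 FPKM over the libraries. In the mesenchymal list 20 of 34 did. None of the 46 hepatocyte genes in the table reached a mean of 1 FPKM over the libraries. Alb (albumin) was at 0.0108 FPKM with vehicle, Afp (alpha-fetoprotein) at 0.0983, Hnf4a (a hepatocyte transcription factor) at 0.0186 and Krt19 (a bile duct keratin) at 0.102. The pluripotency factors Nanog and Pou5f1 were at 0.0277 and 0.0211 FPKM, and Prom1, which encodes the stem cell marker CD133, at 0.00357. The Sox2 row shares its locus with other rows, and reads from overlapping genes were not separated. Sox2 was measurable, at 3.20 FPKM with vehicle, 7.44 with ATRA, 0.575 with SAHA and 0.548 with both. Tlr4, the receptor for bacterial lipopolysaccharide, was at 5.09, 5.08, 0.466 and 0.333 FPKM in the same order. Among genes of other cell types, 1 macrophage gene, 2 endothelial genes, 0 lymphocyte genes and 0 erythroid genes had a mean of 1 FPKM or more. Cd68 was the macrophage gene, and Flt1 and Egfl7 were the endothelial ones.

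The first comparison asked what ATRA alone did. Dhrs3, a retinaldehyde reductase that is induced by retinoic acid, was at 0.0780 FPKM with vehicle and 15.5 with ATRA (chromosome 4, 144892827 to 144928209, plus strand, mm10). Aldh3a1, an aldehyde dehydrogenase, was 12.2-fold higher at 29.7 FPKM. Tgm2, the tissue transglutaminase gene and a classical retinoid target on chromosome 2 (158116402 to 158146436, minus strand), was 3.69-fold higher at 14.7 FPKM. Interferon-stimulated genes were lower, among them Usp18 (1.98 FPKM against 10.1), Ifit1 (2.35 against 9.85) and Irf7 (3.20 against 11.3). Of 8616 counted genes, 79 were higher and 103 lower. Without the 148 small RNAs among them, 43 were higher and 76 lower, and 90% of the remaining genes lay between -0.42 and 0.45 on the log2 scale.

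Few of the counted retinoid targets passed the 2-fold mark with ATRA. Of 9 counted retinoic acid receptor targets, 2 were higher, 0 were lower and all 9 had a ratio above 0. Their median log2 ratio was 0.53, above all 10000 random lists matched on expression. Besides Dhrs3 (3.94) and Tgm2 (1.66), the leading members were Nrip1 at 0.70 and the receptor gene Rarg at 0.64. Other classical targets were at low levels. Rarb was at 0.747 FPKM with vehicle and 1.11 with ATRA, and Cyp26a1 at 0.0401 and 0.0283. Cyp26b1 was at 0.0265 and 0.377, a rise that the scale of FPKM + 1 understates. Of the 30 listed targets, 13 were at 1 FPKM or more with ATRA and 9 with vehicle. The xenobiotic list, which holds aryl hydrocarbon receptor targets, had a median of 0.65 with 4 of 13 members higher: Aldh3a1, Cyp1a1 (1.30), Nqo1 (1.29) and Gsta4 (1.19). NRF2 antioxidant genes had a median of 0.52 with 4 of 28 higher, led by the glutathione reductase gene Gsr at 1.38. Both of these medians lay above all the random lists, and the lists share Nqo1 and Gsta4. The TGF-beta target list stood at 0.37, at the 100th percentile, and its members Id2 and Id1, inhibitors of differentiation, were at 21.1 FPKM against 3.44 and at 13.4 FPKM against 4.58. Bile duct and progenitor genes had a median of 0.65, with 1 of 8 higher (Sox4, 8.70 FPKM against 3.24). With no filter on low values, bile duct and progenitor genes in ATRA against vehicle had a median of 0.0105, at the 91.6th percentile, inside the middle 95%.

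Prl2c2, Prl2c3, Prl2c4 and Prl2c5, which encode proliferin-type prolactin family proteins, were at 54.3, 28.2, 24.1 and 57.3 FPKM with ATRA, and Prl2c1 was at 52.1. These paralogs are near-identical, so the split of reads between them is uncertain. Their vehicle values were 6.46, 5.79, 0.341, 6.77 and 6.05 FPKM. Ckb, the brain creatine kinase gene, was 4.25-fold higher and Csn3, a casein gene, was at 8.46 FPKM against 0.768. Scarna10, a small RNA, was also among the 12 highest (78.8 FPKM against 21.3).

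Interferon-stimulated genes formed the clearest lower group with ATRA. Of 26 counted members, 14 were lower and 0 higher, and their median was -1.07, below all the random lists. Every comparison with vehicle rests on the same single vehicle library. In the combination against SAHA, 0 of the 26 passed the 2-fold mark, with a median of 0.03 inside the middle 95%. With SAHA alone 25 of the 26 were already lower than with vehicle, so that pair is a limited check. Oas3 was at 3.49 FPKM against 13.1 and Ifi44 at 1.91 against 7.45. Samd9l, an interferon-inducible gene outside the list, was at 2.35 FPKM against 9.30. The Ly6 family genes Ly6c1 and Ly6c2, which are paralogs that share reads, stood at 8.41 and 7.97 FPKM against 27.2 and 25.6 with vehicle. Ppp1r15a, which encodes the phosphatase subunit GADD34, was at 5.56 FPKM against 27.0 and Ddit3, which encodes the transcription factor CHOP, at 8.34 against 25.4. The unfolded protein response list that holds both genes had a median of 0.18, at the 98.8th percentile, with 19 of 28 members above 0, 0 higher and 3 lower. As the mean of its members, the value for unfolded protein response genes in ATRA against vehicle was 0.00938, at the 24.6th percentile, inside the middle 95%. Ribosome biogenesis genes had a median of -0.31, below all the random lists, with 0 of 29 past the 2-fold mark. The histone gene Hist2h2aa2 (1.43 FPKM against 9.10) and the small RNA Scarna3b (log2 ratio -1.62) completed the 12 lowest genes.

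The second comparison asked what SAHA alone did. H1f0, the replacement linker histone gene that HDAC inhibitors are known to induce, was 4.18-fold higher (126 FPKM against 30.2; chromosome 15, 79028450 to 79030504, plus strand). Ccnd1, which encodes cyclin D1, was at 0.674 FPKM against 37.0 with vehicle (chromosome 7, 144929931 to 144939925, minus strand). Mitosis genes, histone genes, interferon-stimulated genes, amino acid response genes and mesenchymal genes were lower as groups. Cdkn1a, the p21 gene, was at 3.35 FPKM with vehicle and 3.95 with SAHA. Of 8616 counted genes, 679 were higher and 1381 lower, and the median log2 ratio of all counted genes was -0.12. After each library was centred on its median ratio, 881 were higher and 1157 lower, so that the higher share of the counted differences went from 33.0% to 43.2%.

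Genes high with SAHA had varied functions. Ckb was at 93.3 FPKM against 7.73 and Cadm4, a cell adhesion gene, at 9.44 against 0.0575. Gsta4, a glutathione transferase gene, was 15.7-fold higher, and Cotl1, which encodes an actin-binding protein, was at 11.9 FPKM against 0.752. Akap12, a kinase scaffold gene, was 8.84-fold higher and Pld3, a lysosomal nuclease gene, 10.0-fold higher. Atox1, a copper chaperone gene, was 7.05-fold higher at 131 FPKM. Among immediate early genes, 8 of 28 were higher and 8 lower: Junb was at 82.8 FPKM against 11.0, Egr1 at 34.1 against 4.92 and Klf2 at 19.9 against 2.54, while Myc was at 6.97 against 44.7. Of the 24 counted genes listed as induced by HDAC inhibitors, 8 were higher and 5 lower. The median of that list was -0.15, inside the middle 95% of random lists. Its members Txnip and Rhob were at 69.5 FPKM against 9.71 and at 114 FPKM against 17.2. Histone deacetylase genes differed in direction: Sirt7 was at 6.49 FPKM against 0.801, Hdac6 at 4.53 against 1.21 and Hdac3 at 10.7 against 4.81, while Hdac7 was at 0.394 against 3.31. Among the 12 highest, 2 genes were listed at 0 with vehicle: the histone gene Hist1h2ap (12.6 FPKM), which overlaps another histone gene in the table, and the small RNA AF357425 (9.01 FPKM). Scarna10, at 158 FPKM, was also among the 12.

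Cell division genes were low with SAHA. Of 40 counted G2/M and mitosis genes, 32 were lower and 0 higher, with a median of -1.21, below all the random lists. Mki67, the proliferation marker, was at 3.39 FPKM against 27.2, and Cdc20 and Ccnb2 were at 1.54 against 9.44 and at 2.65 against 11.4. Of 36 histone genes, most of them made during DNA replication, 29 were lower and 1 higher, with a median of -1.65. Hist1h3a was at 118 FPKM against 627 and Hist1h2bk at 407 against 1952. G1/S and DNA replication genes had a median of -0.58 at the 0.260th percentile, with 7 of 34 lower, among them the thymidine kinase gene Tk1 at -2.60. With no filter on low values, the median of G1/S and DNA replication genes in SAHA against vehicle was -0.38, at the 2.62th percentile, inside the middle 95%. With ATRA alone, the 34 counted members had a median of 0.24, at the 100th percentile, with 32 above 0 and 0 past the 2-fold mark. Of 15 genes listed as repressed by HDAC inhibitors, 10 were lower, with a median of -1.18. Besides Ccnd1 and Myc, they included Cflar (0.883 FPKM against 11.5) and Bcl2l1 (2.53 against 21.4), which protect cells from apoptosis.

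The SAHA library also differed in RNA composition. The row Gm20594, chosen for mention after its values were seen, held 33.9% of all FPKM in the SAHA library, against 18.0% with vehicle, 16.6% with ATRA and 10.3% with both compounds. Its annotated transcript, 449 bases long, matched the mitochondrial 16S ribosomal RNA gene mt-Rnr2 at 88.5% identity over 435 bases. FPKM is divided by transcript length, so for a transcript this short these shares of FPKM overstate the shares of reads. Malat1, a nuclear long noncoding RNA, was at 141 FPKM with SAHA, 3.93-fold the vehicle level, at 25.9 with ATRA and at 55.6 with both. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was at 6.38 FPKM with vehicle, 2.53 with ATRA, 49.0 with SAHA and 5.16 with both. The same sequence search listed no match to mitochondrial ribosomal RNA for the GENCODE transcripts of Lars2.

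Interferon, inflammatory and metabolic groups were also low with SAHA. Of 26 interferon-stimulated genes, 25 were lower, with a median of -2.27. Ifitm3 stood at -3.31 and Oas3 was at 0.400 FPKM against 13.1. The interferon-inducible genes Mnda, Ifi204, Ifi205 and Mndal, which form 1 family that shares reads, were at 0.189, 0.120, 0.185 and 0.206 FPKM against 24.5, 19.8, 21.6 and 20.3 with vehicle. NF-kB and inflammatory genes had a median of -1.87 with 7 of 10 lower, among them the adhesion molecule gene Vcam1 (0.445 FPKM against 12.3). Amino acid response genes had a median of -1.69 with 21 of 27 lower. Nupr1, a stress-induced nuclear protein gene, was at 2.14 FPKM against 58.5, and Mthfd2 and Cth, genes of one-carbon and sulfur amino acid metabolism, were at 2.38 against 24.2 and at 0.864 against 11.9. The medians of these 3 groups lay below all the random lists.

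Mesenchymal and stem cell markers completed the picture with SAHA. Of 20 mesenchymal genes, 13 were lower and 0 higher, with a median of -1.32, again below all the random lists. Mmp14, a membrane metalloprotease gene, was at 0.178 FPKM against 15.2, Sparc, a matrix protein gene, at 2.65 against 33.4 and Prrx1 at 0.177 against 8.97. Outside this list, Serpinh1, the collagen chaperone gene, was at 4.25 FPKM against 80.3. Cd34 was at 2.29 FPKM against 50.8 and Ly6a, which encodes the antigen Sca-1, at 0.819 against 28.2. Igfbp4, which encodes an IGF-binding protein, was at 1.76 FPKM against 56.1, and the membrane protein gene Emp3 at 0.812 against 24.9. Of 14 liver cancer stem cell markers, 7 were lower, with a median of -0.98 at the 0.0700th percentile, including Twist1 (0.701 FPKM against 7.62), Tlr4 (-2.05) and Yap1 (-1.79). When markers below the filter were included, the median for liver cancer stem cell markers in SAHA against vehicle was 0.000176, at the 60.9th percentile. With ATRA alone, the 14 counted markers had a median of 0.15, at the 98.8th percentile, with 1 higher and 0 lower. Of 7 genes of retinoid metabolism and transport, 4 were lower, with a median of -1.24 at the 0.435th percentile, and the retinoid-binding protein gene Crabp1 was at 21.9 FPKM against 85.4. With no filter on low values, retinoid metabolism and transport in SAHA against vehicle stood at -0.0593, at the 4.89th percentile, inside the middle 95%. The retinoic acid receptor targets, with Rarg at -1.70, had a median of -0.66 inside the middle 95%, with 2 of 9 lower.

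**Figure D1:**
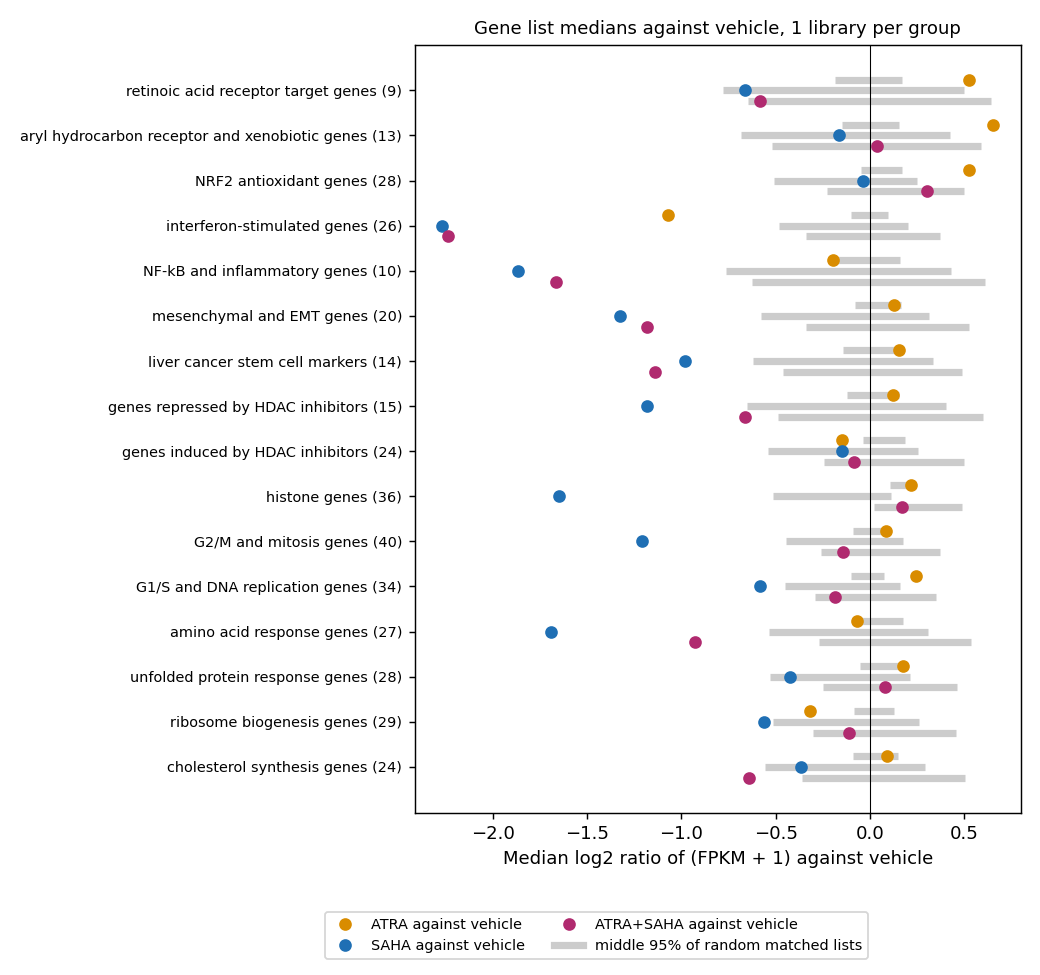
Median log2 ratio of (FPKM + 1) against vehicle for 16 gene lists, with the number of counted members in brackets; points are medians for ATRA, SAHA and ATRA+SAHA, and grey bars are the middle 95% of 10000 random lists matched on expression. The mitosis list stands at -1.21 with SAHA and at -0.14 with both compounds, while the interferon-stimulated list stands at -2.27 and -2.24.

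The third comparison set the combination against vehicle. Ddit3 was 16.2-fold higher (411 FPKM against 25.4), and Hspa5, the gene of the endoplasmic reticulum chaperone BiP, was 7.79-fold higher (367 FPKM against 47.1; chromosome 2, 34771970 to 34777547, plus strand). Ccnd1 was as low as with SAHA alone, at 0.723 FPKM, and S100a4, a calcium-binding protein gene associated with metastasis, was at 18.6 FPKM against 557 (chromosome 3, 90603771 to 90606045, plus strand). H1f0 was 5.43-fold higher at 164 FPKM. Of 8616 counted genes, 954 were higher and 1089 lower. G2/M and mitosis genes had a median of -0.14 with 1 of 40 lower, at the 10.1th percentile, and histone genes had a median of 0.17 with 1 higher and 1 lower of 36.

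Several genes that were high with SAHA were also high in the combination. Cotl1 was at 17.4 FPKM, Cadm4 at 8.05, Ckb at 68.7 and Fam117a at 10.2 against 0.239 with vehicle. Snupn, which encodes a nuclear import adaptor, was at 16.3 FPKM against 1.30 and Egr1 at 42.1 against 4.92. Atg12, an autophagy gene, was at 35.4 FPKM against 3.68 and at 14.4 with SAHA alone. Ifrd1, a transcriptional coregulator gene, was at 239 FPKM against 31.5 and at 22.7 with SAHA alone. Hist1h2ap (93.1 FPKM, and 12.6 with SAHA alone) and the small RNA Scarna17 (19.7 FPKM, and listed at 0 with SAHA alone) were listed at 0 with vehicle. Unfolded protein response genes had 11 of 28 members higher and 3 lower, with a median of 0.08 at the 40.8th percentile. Besides Ddit3 and Hspa5, Creld2 was at 10.9 FPKM against 1.84 and Sdf2l1 at 16.3 against 3.77.

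Among the low genes of the combination, interferon-stimulated genes had a median of -2.24 with 23 of 26 lower. Mnda, Ifi204, Ifi205 and Mndal were at 0.289, 0.167, 0.273 and 0.213 FPKM. Ly6a, Ly6c1 and Ly6c2 were at 0.352, 0.398 and 0.348 FPKM. Mat2a, the gene of the enzyme that makes S-adenosylmethionine, was at 0.880 FPKM against 33.8. Angptl2, which encodes an angiopoietin-like protein, was at 0.426 FPKM against 22.2, and the galectin-binding protein gene Lgals3bp at 0.114 against 15.3. Mesenchymal genes had a median of -1.18 with 11 of 20 lower, and liver cancer stem cell markers a median of -1.14 with 7 of 14 lower. With no filter on low values, liver cancer stem cell markers in ATRA+SAHA against vehicle stood at -0.0106, at the 19.5th percentile. Cholesterol synthesis genes had a median of -0.64 at the 0.0900th percentile with 7 of 24 lower, among them Idi1 (3.16 FPKM against 15.4). Hypoxia and glycolysis genes had a median of -0.60 at the 0.0200th percentile, with Ldha, the lactate dehydrogenase gene, at 49.7 FPKM against 142 and the lactate transporter gene Slc16a3 at 1.72 against 10.5.

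**Figure D2:**
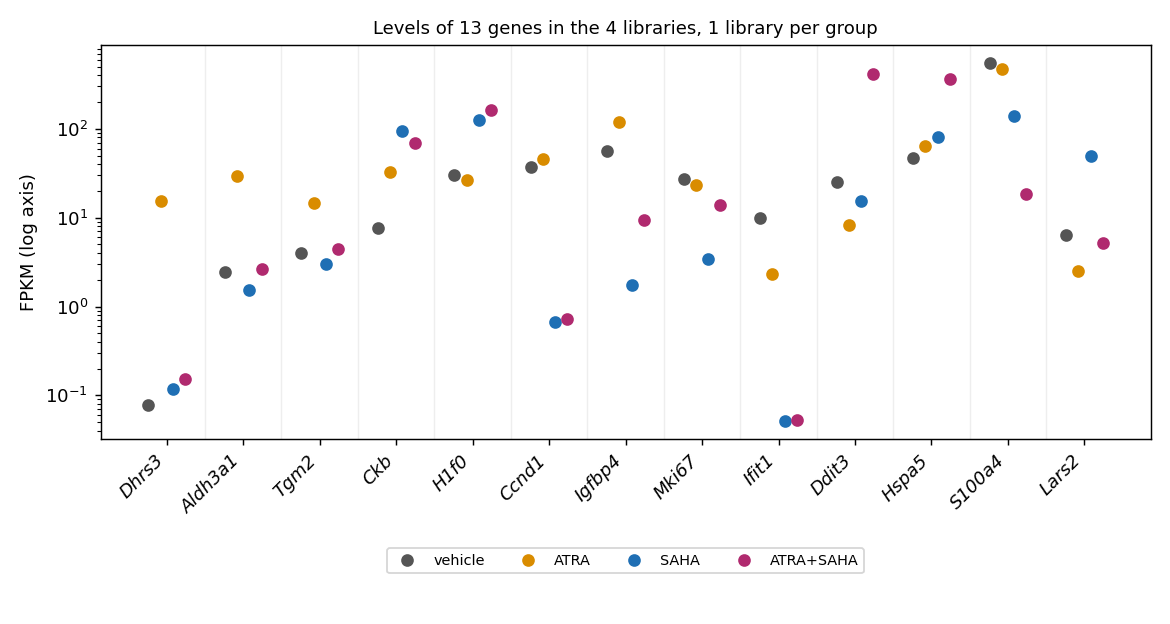
FPKM on a log axis of 13 genes in the vehicle, ATRA, SAHA and ATRA+SAHA libraries, 1 point per library. Dhrs3 is at 15.5 FPKM with ATRA and at 0.153 with both compounds, and Ddit3 is at 411 FPKM with both compounds and between 8.34 and 25.4 in the other libraries.

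The combination was next set against each compound alone, which asks what the other compound added. Against SAHA, 262 genes were higher and 80 lower. The median log2 ratio of all counted genes was 0.14. After centring, 187 were higher and 116 lower, so the higher share went from 76.6% to 61.7%. G2/M and mitosis genes were higher as a group, with 25 of 40 members higher, 0 lower and a median of 1.07. Mki67 was at 13.7 FPKM against 3.39 with SAHA, Hmmr at 9.74 against 2.22 and Top2a at 35.6 against 11.4. Histone genes had 29 of 36 members higher and a median of 1.99, with Hist2h2ab at 172 FPKM against 26.9. The medians of both lists lay above all the random lists. The Gm20594 row held 10.3% of all FPKM in the combination library and 33.9% in the SAHA library.

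Stress genes also separated the combination from SAHA alone. Of 28 unfolded protein response genes, 10 were higher and 0 lower, with a median of 0.47 at the 99.9th percentile. They included Ddit3 (411 against 15.6 FPKM), Hspa5 (367 against 81.0), Trib3 (8.03 against 0.946) and Ppp1r15a (log2 ratio 1.97). Ppp1r15a was nonetheless lower in the combination than with vehicle (log2 ratio -1.11). Ddit3 overlaps Mars in the table, and Mars itself was at 2.91 FPKM in the combination and 3.37 with SAHA. Amino acid response genes had a median of 0.58 with 7 of 27 higher, among them Nupr1 (28.5 against 2.14 FPKM) and the transcription factor gene Atf4 (76.6 against 20.3). Against vehicle, the amino acid response list was below all the random lists in the combination, with a median of -0.93, 12 of 27 lower and 1 higher. Ifrd1 was 10.5-fold higher. Lower than with SAHA were Lars2 (5.16 against 49.0 FPKM), S100a4 (18.6 against 138), the protease inhibitor gene Timp1 (log2 ratio -2.67), the metallothionein gene Mt1 (76.4 against 353) and Mat2a (0.880 against 6.24). Scarna17 and Hist1h2ap were among the 6 highest, and AF357425 was listed at 0 in the combination. Retinoic acid receptor targets had a median of 0.04 at the 21.7th percentile, with 0 of 9 past the 2-fold mark.

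Against ATRA, the combination had 901 genes higher and 1029 lower. Retinoic acid receptor targets were lower, with 6 of 9 past the 2-fold mark and a median of -1.60 at the 0.0100th percentile. Dhrs3 was at 0.153 FPKM against 15.5, Tgm2 at 4.45 against 14.7 and Rarg at 2.97 against 14.2. Prl2c1, Prl2c2 and Prl2c5 were at 0.534, 0.520 and 0.580 FPKM against 52.1, 54.3 and 57.3, and Prl2c3 was near 0 against 28.2. Ccnd1 was at 0.723 FPKM against 45.3 and S100a4 at 18.6 against 467. Among the high genes were Ddit3 at 5.46 on the log2 scale, Ifrd1 at 3.71, Egr1 at 3.57 and Snupn at 3.19. Hist1h2ap and Scarna17, listed at 0 with ATRA, were also among the 6 highest. The TGF-beta target list had a median of -1.08 with 11 of 18 lower, with Id2 at 3.92 FPKM against 21.1.

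The design holds each compound's effect in 2 pairs that share no library. SAHA against vehicle and ATRA+SAHA against ATRA had 475 genes higher in both, where independent lists would share 71.0, and 803 genes lower in both, where 165 would be shared. Across genes, which are not independent replicates, Pearson's r was 0.78, or 0.84 without small RNAs. ATRA against vehicle and ATRA+SAHA against SAHA had 11 genes higher in both (2.40 for independent lists) and 8 lower in both (0.956), with r = 0.11. In the second pair, 2 of the genes higher with ATRA were lower, and 13 of the genes lower with ATRA were higher. Without small RNAs, 1 gene was higher in both ATRA pairs (1.07 for independent lists) and 5 were lower in both (0.530), while 1 and 5 had opposite directions. Igfbp4, the gene higher in both, was at 56.1 FPKM with vehicle, 118 with ATRA, 1.76 with SAHA and 9.34 with both. The 5 genes lower in both were Mat2a, Lars2, F2rl1, Nppb and Gm21312, of which the last 3 were chosen for mention after their values were seen. F2rl1, a protease-activated receptor gene, was at 3.59, 0.717, 7.24 and 1.34 FPKM, and Nppb, a natriuretic peptide gene, at 4.43, 1.31, 12.4 and 3.93. Gm21312 was at 4.24 FPKM with vehicle and 1.08 with SAHA, and near 0 in the other 2 libraries.

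**Figure D3:**
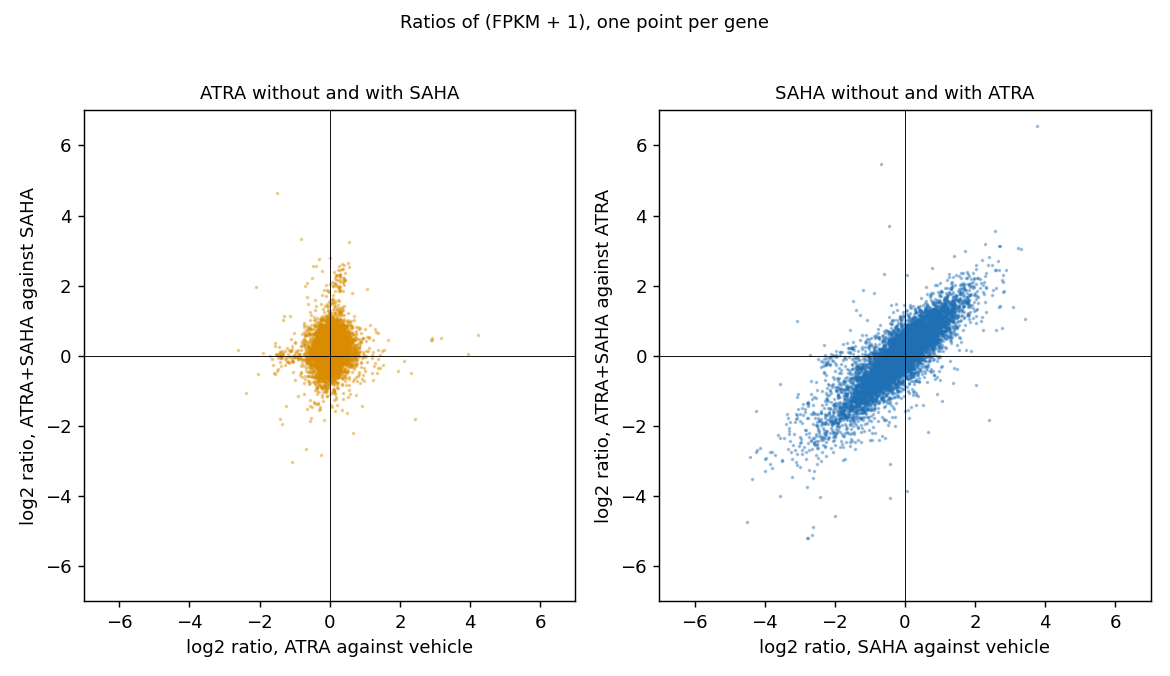
Each point is 1 of 8468 genes without small RNAs; the x axis is the log2 ratio of (FPKM + 1) for a compound against vehicle and the y axis is the ratio for the same compound added to the other one. Pearson's r across genes is 0.84 for SAHA and 0.11 for ATRA.

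The combination was also set against the sum of the single-compound log2 ratios. The departure was 1 or more above the sum for 404 genes and 1 or more below it for 149. Its median over all counted genes was 0.15, so the departures leaned upward across the libraries as a whole. Each departure draws on 4 single libraries, against 2 for a ratio, so noise passes the same mark more easily. The departure was highest for Ddit3 (6.13), Ifrd1 (4.16), Ppp1r15a (4.06) and the noncoding host gene Snhg5 (3.02). Of these, Ppp1r15a was lower in the combination than with vehicle (log2 ratio -1.11). The small RNAs Scarna3b (3.53) and Scarna17, which was listed at 0 in the other libraries, were also among the 6 highest. The departure was lowest for Csn3 (-4.23), Dhrs3 (-3.90), Prl2c4 (-3.63), Mt1 (-2.87), Id2 (-2.81) and AF357425, which was listed at 0 in all but the SAHA library. Histone genes had a median departure of 1.79 with 28 of 36 members above the mark, and G2/M and mitosis genes 1.02 with 22 of 40. Interferon-stimulated genes had a median departure of 1.22 with 17 of 26 above the mark. The medians of that list with ATRA and with SAHA were both below 0, and Ifit1 was at 2.35 FPKM with ATRA, 0.0517 with SAHA and 0.0530 with both, near the floor of the scale. Retinoic acid receptor targets had a median departure of -0.59, and NRF2 genes one of -0.43, both below all the random lists.

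There were 264 medians, from 44 lists with at least 5 counted members in 5 comparisons and the departure from additivity. Of these, 33 lay above and 90 below the middle 95% of random lists. By construction 5% of the random lists lie outside it. That share is not a chance rate for the fixed lists, because their members can vary together in any library. The medians also reuse the same libraries and lists, so these counts are not a test of treatment effects. With ATRA 14 lists lay above and 12 below, with SAHA 2 above and 16 below, and with the combination against vehicle 0 above and 18 below.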

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

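The genes in the first paragraph were picked by a rule of opposite direction after the data were seen, and of the tests in the later paragraphs, all but the length trend and the check of ATRA activity were chosen after the result was seen. In each gene below, 1 compound's ratio was 2-fold or more in one direction without the other compound and 2-fold or more in the opposite direction with it. With 1 library per group this difference was not tested, and the value given is the departure from additivity on the log2 scale. For ATRA, the genes were Ddit3 (6.13), Ppp1r15a (4.06), Nfil3 (2.45), Tsc22d3 (2.37), Atf3 (2.26) and Csn3 (-4.23), with the small RNAs Scarna3b (3.53) and Scarna3a (2.29). For SAHA, they were Csn3 and Nfil3 at the same values, Snhg5 (3.02), Snhg12 (2.70), Sepw1 (2.09) and Tinagl1 (-2.34), with Scarna3b and Scarna3a again. Csn3 was at 0.768 FPKM with vehicle, 8.46 with ATRA, 8.39 with SAHA and 1.68 with both. Nfil3, a circadian and immune transcription factor gene, was at 10.9, 3.81, 3.86 and 9.70 FPKM in the same order. Tsc22d3, a glucocorticoid-induced gene, was at 18.6, 6.71, 2.53 and 6.19 FPKM. The matrix protein gene Tinagl1 was at 24.2, 46.5, 51.7 and 18.6 FPKM, and the selenoprotein gene Sepw1 at 23.4, 15.0, 10.5 and 31.1.

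Mitosis genes were lower in the SAHA library and near the vehicle level with both compounds. A difference in scaling, including residual ribosomal RNA taking reads, would move genes matched on expression alike, but the list lay below all the matched random lists. Its median with SAHA after centring was -1.09. Centring moves the list and its random lists alike, so it adds no separate test of that position. A transcript length bias is argued against by the median of -1.21 left after the length trend was removed, the same as before. Swapped labels of the SAHA and combination libraries cannot be told apart from the labels as given, since the retinoic acid receptor targets, which would show the swap, differed by a median of 0.0430 at the 21.7th percentile. An effect of adding ATRA to SAHA may also underlie the pattern and stays untested, because 1 library stands for each culture.

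Of the 79 genes higher with ATRA alone, 11 were also higher in the combination than in SAHA, and without small RNAs 1 of 43 was. Chance high values in the single ATRA library cannot be told apart from a response for most of these genes. The retinoic acid receptor targets had a median of 0.53 in ATRA against vehicle, above all the random lists, but hold 2 of the 43 genes. With 9 counted members, that list could not have held most of the 43, so it could not decide the question for them. A combination culture without active ATRA remains a possible explanation: over 16 ATRA genes that SAHA left within 1.5-fold of vehicle on the scale of FPKM + 1, the median ratio of the combination to SAHA, taken in the ATRA direction, was 0.0283, and the middle 50% ran from -0.26 to 0.51. SAHA blocking the response to ATRA predicts the same value, so it stays open too. The receptor gene Rarg had a log2 ratio of -1.70 in SAHA against vehicle, and Rxra was at 0.826 FPKM with SAHA against 2.18.

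Unfolded protein response genes were higher with both compounds than with SAHA. A scaling difference between the SAHA and combination libraries would move genes matched on expression alike. After centring the list had a median of 0.32 against SAHA, at the 99.9th percentile of matched random lists. Their range was -0.11 to 0.23. Centring moves the list and its random lists alike, so this percentile was nearly fixed by its value before centring and is no separate test. One factor per library could not set the list apart from matched lists, so the position argues against scaling as the whole explanation in this comparison. Scaling could account for part of the median, which was 0.47 before centring. Against vehicle its median was 0.04, at the 39.7th percentile, so the list did not stand apart there. The deciding comparison had first been set against vehicle, then against SAHA, and in the end both were required. By that last rule the test was undecided, but the value against vehicle does not bear on scaling between SAHA and the combination. The swapped labels left open for the mitosis genes would bear on this pattern too, and a response to the combination stays untested with 1 library for each culture.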

How the results depend on the processing

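Leaving out small RNAs was chosen after the data were seen. Centring kept all 14 counts within 1.5-fold of the values reported, and so did dropping the filter. Of the counts of genes in each comparison (higher then lower), a pseudocount of 0.1 gave 130 higher for ATRA, 1099 higher for SAHA, 1484 higher for the combination against vehicle, 1410 higher against ATRA, and 490 and 185 against SAHA. Of genes 2-fold or more in both ATRA pairs it gave 35, of genes 2-fold or more in both SAHA pairs 2046, and for the departure from additivity 1012. The filter at 5 FPKM gave 37 and 29 for ATRA, 337 and 596 for SAHA, 502 and 409 for the combination against vehicle, 435 and 419 against ATRA, 165 and 40 against SAHA, 12 and 588 genes in both pairs of ATRA and SAHA, and 277 departures. Without small RNAs, 43 genes were higher with ATRA and 6 were shared by both ATRA pairs. Of 123 list medians outside the random range, 115 stayed outside on the same side with the 0.1 pseudocount, 119 without small RNAs, 94 as means, 85 without the filter and 70 with the 5 FPKM filter, where lists with fewer than 5 members left, among them retinoic acid receptor targets and interferon-stimulated genes, gave no value. Centring moves a list and its random lists alike, so it cannot test their relative position. Those that took the opposite sign did so at small size. With no filter these were liver cancer stem cell markers in SAHA against vehicle (0.000176), MHC class I antigen presentation in ATRA+SAHA against ATRA (-0.0158) and lysosome and autophagy genes in ATRA+SAHA against SAHA (0.00539). With the 5 FPKM filter it was heat shock genes in departure from additivity (0.0939), and as means PPAR target genes in SAHA against vehicle (-0.00757), the lysosome genes again (0.0667), genes induced by HDAC inhibitors in departure from additivity (0.0229), Wnt/beta-catenin targets in departure from additivity (0.0243) and abundant noncoding RNAs in departure from additivity (0.109). The cause was not tested. All 108 ratios of genes named by rank kept their direction and the 2-fold mark under centring and under the 0.1 pseudocount. For ratios of 2 libraries this outcome was largely fixed beforehand. A smaller pseudocount enlarges such a ratio, and centring moved them by much less than their size. The planned setting based on deposited intervals was not run, since the table used here holds none. No paired analysis was possible because the groups share 1 replicate number and the counts come from no test. An additive fit over the 4 libraries was not run, since it would take the departures from additivity as its error. Depth limits genes near 0 FPKM, where exact zeros occur.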

Other observations

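Genes of lipid, apoptosis and neuronal function add to the picture. With ATRA, fatty acid and lipid synthesis genes had a median log2 ratio of 0.27 at the 100th percentile, with 0 of 20 past the 2-fold mark, and against ATRA the combination had 9 of 20 lower with a median of -0.77. Fasn, the fatty acid synthase gene, was at 8.37 FPKM with vehicle, 9.72 with ATRA, 3.76 with SAHA and 2.27 with both. Neuronal genes had 3 of 8 members higher and 1 lower with SAHA, and their median was -0.28, inside the middle 95% of random lists. In the combination against ATRA, 4 of the 8 were higher and 0 lower, with a median of 0.99 above the middle 95%. With SAHA against vehicle, Ncam1 was at 4.72 FPKM against 0.237, Uchl1, a neuronal ubiquitin hydrolase gene, at 3.55 against 0.0801, and Vgf stood at 1.80 on the log2 scale. Spp1, the osteopontin gene, was at 336, 566, 939 and 433 FPKM in the vehicle, ATRA, SAHA and combination libraries. Calr, the calreticulin gene, was at 27.3, 37.4, 101 and 74.5 FPKM in the same order. Ribosome biogenesis genes had a median of -0.56 with SAHA and -0.11 with both compounds, and Nop56 was at 29.5, 16.6, 3.48 and 5.88 FPKM.

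Among apoptosis genes, Casp8 was at 7.01 FPKM with vehicle, 7.28 with ATRA, 0.684 with SAHA and 0.785 with both. Pro-apoptotic genes had medians between -0.09 and 0.05 in the 5 comparisons. Hypoxia genes included Ndrg1 at 11.3, 5.15, 3.63 and 5.03 FPKM in the same order. Cytosolic ribosomal protein genes had 0 of 52 members past the 2-fold mark with ATRA or SAHA, and 1 with both compounds. Hox genes and hepatocyte genes had 0 counted members. Of 13 listed mitochondrial mRNA genes, 0 were found by symbol among the deposited values, so that list could not be analysed here.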
